A study of Corynebacterium glutamicum R with 3 samples.

How the data were processed

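Total RNA was extracted from exponentially growing cultures of Corynebacterium glutamicum R, wild type and sigD deletion mutant, in 100 ml of medium in a 500 ml flask, per the labels' protocols. Per the same protocols, cDNA was made by reverse transcription from 10 µg of total RNA and labelled indirectly with Cy3 or Cy5. The labels name 3 independent experiments, each hybridised to 1 array together with both strains. The arrays were read with Agilent Feature Extraction. The submitters' processing notes give its version as 10.5.5.1, and per the file headers it was 10.5.1.1. The design of the probes and the source genome are not given in the sources used here.

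Spot brightness and local background were deposited as linear intensity values per channel, per the file headers without normalization for the median signals. The files also hold intensity values from which the scanner software had subtracted the background, per the file headers. The scanner software's log10 ratio of Cy5 to Cy3, made from its processed and dye-normalized signals, was deposited beside them. The authors also deposited a table with 1 value per probe and array. Its columns had Pearson correlations of 0.993, 0.999 and 0.993 with the scanner software's ratio on the log2 scale. Their slopes on that ratio were 0.995, 0.998 and 0.997. The medians were -0.0054, 0.0002 and -0.0031, the last after the sign of array 3 was turned. The authors' values were therefore taken as log2 of Cy5 over Cy3, centred near 0 and not turned by strain as deposited. How that table was normalized beyond the scanner software stays unknown.

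The values reported were computed from the median signal. The plan fixed before the data were examined named the mean signal, and the median signal was used because the tables analysed here have no mean signal column. Background was corrected with normexp (offset 50), and each array was normalized by loess on log2(Cy5/Cy3), with control spots at weight 0. Control spots and spots with an outlier flag (35, 4 and 1 on arrays 1, 2 and 3) were then left out. The 2 spots of a probe were averaged, and the sign of array 3 was turned so that every value is mutant over wild type. The direction was taken from the dyes in the labels. This left 3277 probes with a value on every array, and 1 was left out because both its spots had an outlier flag on an array. The mean over 3 arrays was tested against 0 with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 3277 probes and a threshold of 0.05. The prior had 2.86 degrees of freedom. Normalised levels of each strain were taken per channel after loess and Aquantile normalization and are open to dye bias, since 2 arrays ran one way and 1 the other.

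On simulated spots with 200 changed probes among 3277, built from the real signals of this comparison, the same steps called 78%, 86%, 96% and 100% of the probes changed by 0.5, 1, 2 and 4 on the log2 scale, with 50 probes at each size. Of the 187 calls, 7 (3.74%) were probes that had not been changed. The simulated noise was drawn separately for each array, so these figures leave out probe errors that arrays 1 and 2 share through dye or scan day. In the real data the robust SD of the difference was 0.0896 between arrays 1 and 2, and 0.179 and 0.185 between each of them and array 3. The share of false calls among the real calls is therefore not given by the simulation. The smallest simulated change, 0.5, was above the median absolute log2 ratio of 0.31 among the real calls. Detection at the size of most real calls was therefore not simulated.

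The scanner software's flag for signals well above background was set for 94.4% and 68.5% of the empty Cy3 spots on arrays 1 and 2, and for 0 of them on array 3. It was set for 0 empty Cy5 spots. The flag therefore carries little information on dim probes in Cy3 on arrays 1 and 2, where the wild type was. It was used for the mutant signals of named probes and for 1 alternative. Spots with a Cy3 signal below the local background made up 10.7%, 9.53% and 2.62% of those on arrays 1, 2 and 3.

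The probes to be named were fixed before the data were examined: the 12 largest falls and 12 largest rises in mean log2 ratio among probes past the threshold with the same sign on all 3 arrays. The rule also covered sigD, rsdA, their neighbours on the chromosome and members of 34 gene lists, which could not be looked up because the probes have no gene names and 0 probe IDs matched the reference table. For the same reason 2 IDs are given for each direction and the other probes by rank. The test of neighbouring genes was run over probe numbers, without strand, with 100000 shuffles of the calls.

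Alternatives planned before the data were examined changed the background correction, the normexp offset (10), the normalization within and between arrays, the filter on dim probes, the dye term, the array weights, the prior, the threshold and the source of the values, and left out each array in turn. Alternatives added after the data were seen used the scanner software's background-subtracted signal with loess, a filter at the 99th percentile of the empty spots, and the mean of arrays 1 and 2 as 1 value. The batches that could be seen were the 2 scan days, which coincide with the dye orientation. The fit with a dye term therefore also serves as the fit with scan day as a block. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the figures.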

Results

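Corynebacterium glutamicum R is a Gram-positive soil bacterium used to produce amino acids and other chemicals. SigD is one of its sigma factors, the subunits that direct RNA polymerase to particular promoters, and belongs to the extracytoplasmic function family. The series set the transcripts of a strain with the sigD gene deleted against those of the wild type, both taken in the exponential phase of growth at 33 °C in a rich medium with 1% glucose. The question the comparison addressed was which transcripts differ in level when the sigma factor is missing from growing cells.

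The data were 3 two-colour oligonucleotide arrays, 1 for each of 3 independent experiments. Every array held cDNA of the mutant and of the wild type in different dyes, so each array gave its own mutant to wild type ratio. The mutant was in Cy5 and the wild type in Cy3 on arrays 1 and 2, and the dyes were exchanged on array 3. Each array carried 6864 spots, of which 302 were empty, and 3278 numbered probes were printed in 2 spots each. The median Cy3 signal was 7.72, 7.74 and 8.54 times the median local background on arrays 1, 2 and 3, and the median Cy5 signal was 18.6, 21.5 and 17.2 times its background. No spot was saturated. The number of arrays limits the precision of every value given here.

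The probes carried numbers and no gene names, and the files do not pair the numbers with genes. None of the probe IDs matched an identifier in a table of 3079 genes of C. glutamicum ATCC 13032, a related strain (0 matches). The level of sigD itself, of its anti-sigma factor gene rsdA and of the genes beside them is therefore not reported here, and 0 of the 34 gene lists that had been fixed in advance could be tested. The changes are described by probe, by size and by probe number.

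Loss of sigD went with a very large fall in a few transcripts and with small changes in many others. The probe that fell most was ID_764, with a mean log2 ratio of mutant to wild type of -7.70 ± 1.5 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00243). Its ratio was -8.60, -8.54 and -5.97 on arrays 1, 2 and 3. The mutant signal of this probe was well above background on 2 of the 3 arrays, and the size of its fall was uncertain. The mean was -7.23 to -8.36 over the alternatives for the background and -8.57 without array 3. ID_2154 fell by 5.98 on the log2 scale, with an SD of 0.288 over the 3 arrays (limma, Benjamini-Hochberg adjusted p = 9.79e-05). This was a 63.1-fold difference, and the mutant signal was well above background on 3 of 3 arrays. In the wild type the mean normalised log2 level was 15.19 for ID_764 and 13.95 for ID_2154.

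The next probes in order of fall had mean log2 ratios of -4.34 ± 0.817 and -3.60 ± 0.160 (SD, n = 3), and both passed the limma test with adjusted p of 0.00231 and 9.79e-05. The mutant signal of the first of them was well above background on 1 of 3 arrays, and its mean ran from -3.58 without background subtraction to -6.58 with the scanner software's background-subtracted signal, so its fall has a direction and no exact size. By rank 12 the fall had shrunk to -1.34 on the log2 scale. Of all probes tested, 7 fell and 2 rose by at least 4-fold, and 4 fell and 0 rose by at least 8-fold, among those that passed the test. These counts hold for the reported background correction: ID_2591, the most raised probe, had 3.03 on the log2 scale, above 8-fold, in the scanner software's log ratio, and 3.01 in the authors' deposited table. Without background subtraction the 6th and 7th probes in order of fall had -1.86 and -1.75, under 4-fold.

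The largest rises were smaller than the largest falls. Below these the sizes were alike: of the probes past the threshold, 13 fell and 14 rose by 1 to 2 on the log2 scale. ID_2591 rose by 2.57 ± 0.207 on the log2 scale (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 3.67e-04), a 5.93-fold higher signal in the mutant. ID_1015 rose by 2.24 ± 0.056 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 9.79e-05), a 4.72-fold difference. The 3rd probe in order of rise had a mean log2 ratio of 1.84, and the 12th had 1.23. All 12 lowered and 12 raised probes chosen by the rule for named probes had the same sign on each of the 3 arrays, as that rule required.

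**Figure D1:**
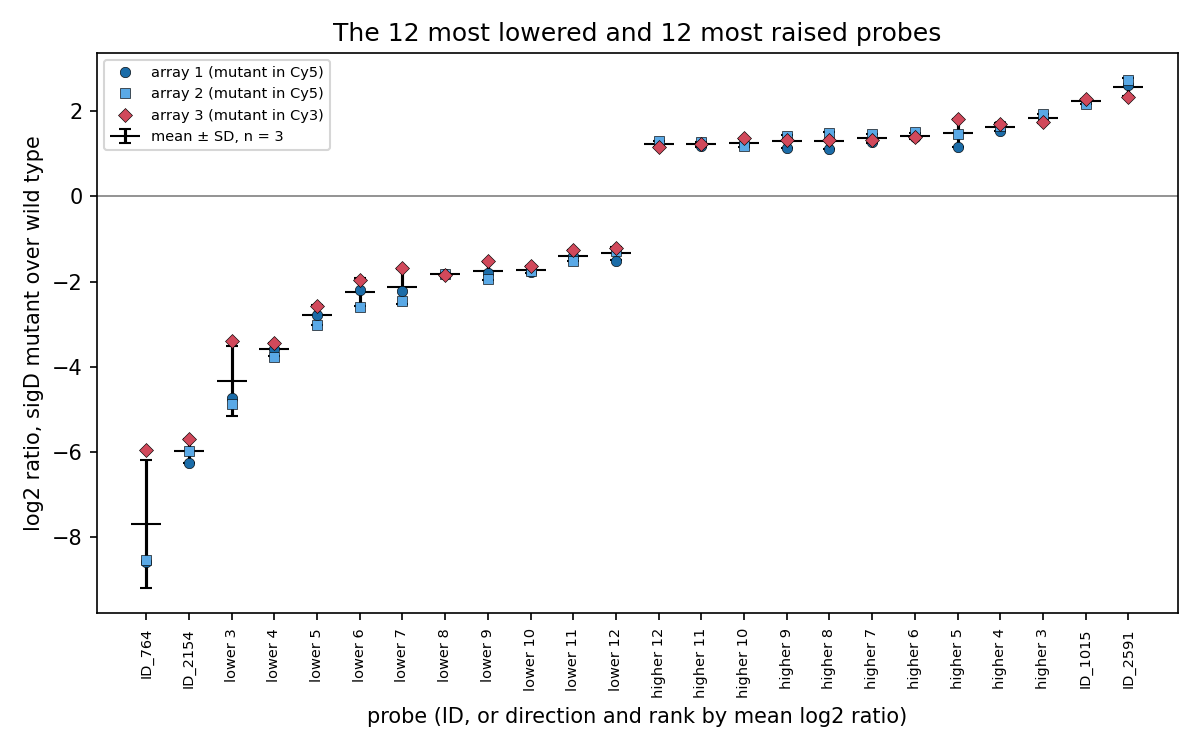
Log2 ratio of mutant to wild type for the 12 most lowered and the 12 most raised probes that passed the test, with 1 symbol per array and the mean ± SD over 3 arrays. The means run from -7.70 for ID_764 to 2.57 for ID_2591, and the largest SD among the 24 probes is the 1.5 of ID_764.

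In total, 841 of 3277 probes tested differed between the strains at a Benjamini-Hochberg adjusted p under 0.05 in limma, which was 25.7% of them. The mutant had the lower level for 405 and the higher level for 436. Most of these differences were small: 805 of the 841 (95.7%) were under 2-fold, and the median absolute log2 ratio was 0.31. The other 36 changed by at least 2-fold, 20 of them lower and 16 higher in the mutant. The total depended on single arrays, being 422 without array 1, 340 without array 2 and 1480 without array 3, and the count at 2-fold or more was 38, 35 and 59. The total was 131 with median centring in place of loess, 1382 with a dye term, 1781 with array weights and 338 with arrays 1 and 2 averaged.

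Ratios from arrays 1 and 2 had a Pearson correlation of 0.93 and a Spearman correlation of 0.86 across probes. Array 3, turned to mutant over wild type, had correlations of 0.75 (Spearman 0.52) with array 1 and 0.68 (Spearman 0.52) with array 2. Before the sign of array 3 was turned, its Pearson correlation was -0.75 with array 1 and -0.68 with array 2, the sign that exchanged dyes give. These values are across probes, which are not independent replicates. Arrays 1 and 2 were scanned on 1 day and array 3 on another, so that scan day and dye orientation cannot be told apart.

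A group of 11 probes was at least 2-fold higher in the mutant on arrays 1 and 2 and lower on array 3. Their median log2 ratios were 1.74, 3.10 and -0.38 on arrays 1, 2 and 3. None of the 11 passed the test (0 probes; smallest limma adjusted p = 0.142, Benjamini-Hochberg). The group was chosen after its values were seen. It includes the 10 probes that had a mean change of at least 2-fold without passing.

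**Figure D2:**
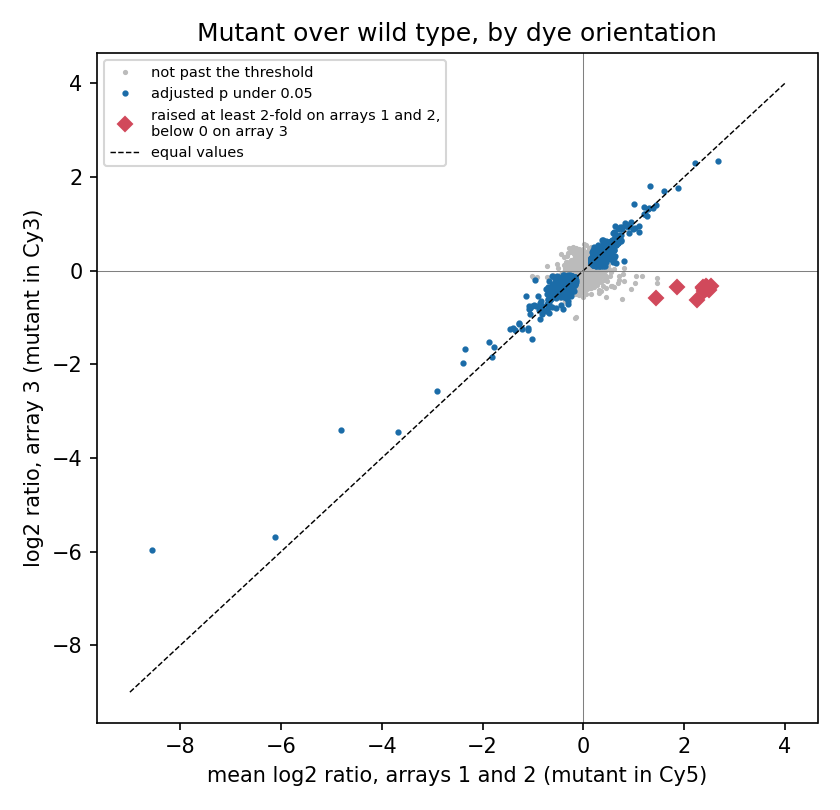
Log2 ratio of mutant to wild type on array 3 (mutant in Cy3) against the mean of arrays 1 and 2 (mutant in Cy5), with 1 point per probe and a dashed line of equal values. The 841 probes past the threshold lie in the lower left and upper right quadrants, and the 11 probes drawn as diamonds lie to the right of 0 and below it.

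Probes with consecutive numbers changed together. The Spearman correlation of the mean log2 ratio between a probe and the next number was 0.37, and it was 0.23 at a distance of 2, 0.12 at 3 and 0.007 at 20. On single arrays the value for consecutive numbers was 0.32, 0.33 and 0.35. Among consecutive numbers, 320 pairs passed the test in the same direction, against a mean of 107.6 after shuffling the calls over the probes. The highest of 100000 shuffles gave 150 pairs, for a one-sided permutation p = 1e-05, the smallest these shuffles can give. The test had been planned over genes in chromosome order and was run over probe numbers, a choice made after the data were seen.

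The probes on either side of ID_764 by number passed the test as lower too, the next number with a fall of 1.33 on the log2 scale and the number before being the 3rd probe in order of fall, of uncertain size, while those 2 numbers away had ratios of 0.09 and -0.09 that did not pass the test. The probes at ranks 5, 6, 7 and 11 of the falls (-2.79, -2.25, -2.12 and -1.39) had consecutive numbers in a run of 5 lowered probes with a mean log2 ratio of -1.81. The mutant signals at ranks 6 and 7 were well above background on 2 of 3 arrays. Their sizes, and with them the mean of the run, are uncertain. Among the rises, the probes at ranks 3 and 10 (1.84 and 1.26) were consecutive, as were those at ranks 11 and 12. Not every named probe had such neighbours. Of the numbers beside ID_2154, 1 passed as lower (-0.63) and 1 did not pass (-0.06). Those 2 numbers away from ID_2154 both passed as lower (-0.25 and -0.39). Both numbers beside ID_1015, which rose, passed as lower (-0.67 and -0.21), and the 1 tested number beside ID_2591 did not pass (0.12). Of the 36 probes that changed by at least 2-fold, 13 had a consecutive number that changed by as much in the same direction, 9 of them lower and 4 higher. Probes past the threshold formed 74 runs of at least 3 consecutive numbers with 1 direction, 42 lower and 32 higher. The runs held 300 probes, 35.7% of those that passed. The longest run held 30 raised probes with a mean log2 ratio of 0.49 (0.37 to 0.66), a 1.40-fold rise. Its mean was 0.56, 0.38 and 0.52 on arrays 1, 2 and 3. The 10 numbers before it had a median log2 ratio of 0.01 and the 10 after it -0.02, with 1 probe past the threshold on each side. The longest run among 1000 shuffles of the calls held 8 probes. The run next in length held 11 lowered probes with a mean log2 ratio of -0.38.

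**Figure D3:**
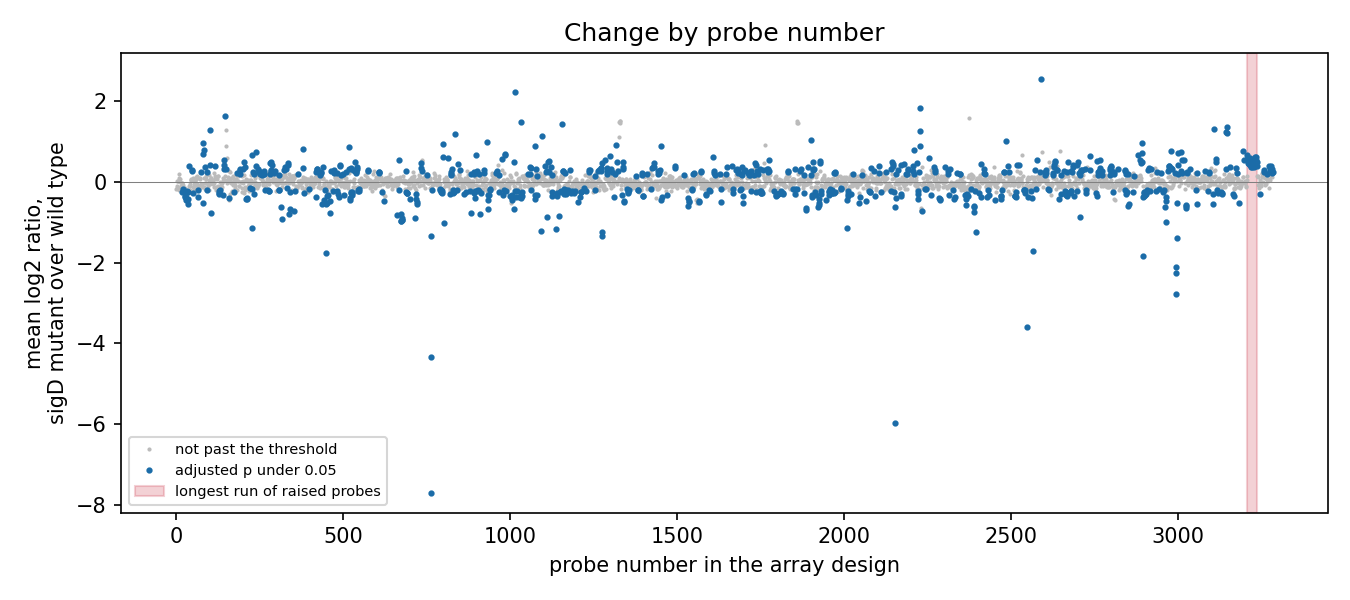
Mean log2 ratio of mutant to wild type over 3 arrays for each probe, in order of probe number, with probes at an adjusted p under 0.05 in dark blue. The shaded band marks the run of 30 raised probes, whose means lie between 0.37 and 0.66.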

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

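The tests on dye bias, on shared cultures, on the 11 probes and on sign assignments were chosen after the results they bear on were seen. One signal outside the main measurement stood out: of 3 numbered control probes, 1 had a Cy5 signal 3.02, 3.83 and 3.02 times that of the empty spots on arrays 1, 2 and 3, above the brightest empty spot in both channels of every array. What this probe detects is not given in the sources used here.

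With the signs of the arrays as the labels give them, 841 probes passed the threshold, and of the 4 ways to assign signs to 3 arrays, 1 gave as many. The highest count among the other assignments was 0. With 4 assignments no share under 0.05 can arise.

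Most of the 841 probes changed by less than 2-fold, a size at which the dyes alone may give a ratio. Among 425 probes chosen on arrays 1 and 2 alone, with ratios of at least 0.3 in size on the log2 scale and a mean under 2-fold, 381 had the same sign on array 3 with exchanged dyes. That share was 89.6% (exact 95% interval 86.4% to 92.4%). It was 78.9% (75.7% to 81.9%) for 692 probes whose smaller ratio on arrays 1 and 2 was from 0.16 up to 0.3 in size. The larger ratio of these probes could exceed 0.3, with the mean again under 2-fold. The intervals treat probes as independent, which they are not. Both shares argue against dye bias as the whole source of such changes. The ratio on array 3 was a median of 0.711 and 0.528 of the mean of arrays 1 and 2 in these sets, so a contribution of the dyes stays open, as does a shrinkage from choosing probes on arrays 1 and 2. Arrays 1 and 2 differed by over 6 SD of their duplicate spots for 48 probes, but duplicate spots carry no labelling or hybridisation error, so this does not show whether both held separate cultures, as the labels state.

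The group of 11 probes was at least 2-fold higher in the mutant on arrays 1 and 2 and lower on array 3. A dye bias alone would give equal ratios on arrays 1 and 2, but the median difference between them was 1.29 on the log2 scale against a robust SD of 0.0896 over all probes, and 10 of the 11 differed. For the other probe the difference was 0.0086, so for it dye bias and a change in the cultures cannot be told apart. The 2 spots of a probe lay 26 rows apart and differed by a median of 0.0749, which argues against a defect at one place of the array. The wild type level differed between arrays 1 and 2 by a median of 1.30, against a robust SD of 0.123 over all probes. The mutant level differed by 0.06 between arrays 1 and 2 and by 3.09 between arrays 2 and 3, where dye and scan day changed too. Levels and ratios come from the same signals, so the 1.30 is the 1.29 seen from the wild type side and not separate evidence. A candidate explanation is expression that varied between cultures apart from the deletion.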

How the results depend on the processing

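The alternatives with background-subtracted signal and loess, with a filter at the level of the empty spots, and with arrays 1 and 2 averaged were chosen after the results were seen, as was the use of probe numbers for the order of genes. The number of probes past the threshold moved from 841 (405 lower, 436 higher) to 131 with median centring (60 lower, 71 higher), to 1382 with a dye term (704 lower, 678 higher), to 1781 with array weights (865 lower, 916 higher) and to 338 with arrays 1 and 2 averaged (153 lower, 185 higher). It was 36 (20 lower, 16 higher) when a 2-fold change was also required, by construction. Array weights were 2.81, 1.29 and 0.275 for arrays 1, 2 and 3. The fit with a dye term left 1 residual degree of freedom. Its error came from arrays 1 and 2 and the prior, so the disagreement of array 3 did not enter it. A larger count there is no sign of more true changes. The same holds for the fit with array weights, in which array 3 counted least. For the remaining alternatives the cause was not tested. Leaving out 1 array gave 340 to 1480 probes, 146 to 713 lower and 194 to 767 higher, and 35 to 59 at 2-fold or more. The 24 named probes kept their direction and stayed past the threshold in all 408 combinations of probe and alternative. They had been chosen as the largest changes in the same data. With the added 2-fold requirement none could fail, since it reused the reported fit, where all 24 exceeded 2-fold. The filters on dim probes also left the ratios unchanged. The sizes of dim probes depended on the background correction: the 3rd, 6th and 7th probes in order of fall ran from -3.58 to -6.58, -1.86 to -2.90 and -1.75 to -2.71, ID_764 from -7.23 to -8.36 and ID_2591 from 2.26 to 3.03. Without array 3, ID_764 was at -8.57. The 36 probes changed by at least 2-fold in the reported fit were past the threshold in every alternative run except median centring, where 34 were. The added 2-fold requirement kept them by construction. Pairs of consecutive numbers called alike stayed above their shuffled mean in each alternative, by 1.66 to 41.4 times. Not run were the median signal as an alternative, since it is the signal used, the brightest probe of a gene, since the files name no genes, and every alternative for sigD, rsdA and the gene lists. With Cy3 at 7.72 to 8.54 times background, ratios of dim probes are uncertain in size.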

Other observations

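The tests on the distance between probe numbers, on signal, on 1 common fold and on the deleted gene were chosen after the results were seen. Those on place on the array were written down before their results were seen.

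Consecutively numbered probes changed together, and 30 consecutive numbers rose as a run. Spots next to each other in a row or column, but not close in number, had correlations of 0.0287 and 0.0295, against 0.37 for consecutive numbers. Spots at the offset most common among consecutive numbers had 0.0182. That offset covered 45.0% of consecutive pairs, and the other offsets were not each matched. Probes spotted next to those of the run had a median log2 ratio of 0.0268. These values argue against place on the array for both, as far as the tested placements reach. Before loess the ratios had Spearman correlations of 0.46, 0.40 and -0.64 with signal on arrays 1, 2 and 3. Loess moved them by a median of 0.0780, close to the spread of duplicate spots (SD 0.0498 to 0.0754). On array 2 the shift was 0.0713, under the largest of these SDs, so array 2 decides nothing. For the mean over arrays the correlation of consecutive numbers was 0.379 before and 0.367 after loess, but trends of opposite sign partly cancel in that mean. On arrays 1 and 3 alone it was 0.360 and 0.378 before and 0.324 and 0.346 after, which argues against that trend as the whole source. A candidate explanation is that probe numbers follow the gene order, so that neighbours include genes of 1 operon: the correlation of 0.367 at distance 1 fell with distance, and this remains a hypothesis because the files give no positions. The 30 probes may share 1 common fold, as a segment present in more copies may give. The variance of their mean ratios was 2.0 times their replicate error variance (95% interval 1.27 to 3.61, treating the probes as independent). The interval lay above 1, the value for members that differ by replicate error alone, and on both sides of the bound of 1.5 set for it. That error variance also holds the shift of the whole run between arrays 1, 2 and 3 (means 0.56, 0.38 and 0.52). A shift that all members share cannot spread them apart, so the ratio is understated and cannot speak for 1 common fold. The values argue against 1 common fold of the 30 probes as measured, although the interval did not clear the bound of 1.5. No test without this shift was run.

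The deleted gene should leave a probe with almost no signal in the mutant, unless the probe lies outside the deleted part. At least 16-fold lower on every array were 2 probes, ID_764 and ID_2154, and 3 in the scanner software's log ratio or with its background-subtracted signal and loess, both of these among them. The mutant signal was well above background on 2 of 3 arrays for ID_764, on 3 of 3 for ID_2154 and on 1 of 3 for the 3rd probe in order of fall, whose fold the background limits. The count by fold cannot say which probe, if any of these, may be sigD.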
